A study of Homo sapiens with 19 samples.

How the data were processed

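QUASARR-seq libraries from K-562 cells were compared, with RNA and DNA reads of the barcodes named paBC and eaBC. Per the labels, 20 µg of plasmid were used per electroporation, 5 electroporations made a technical replicate and 2 technical replicates a biological one, and cells were harvested after 6 h. The pool of each technical replicate was split for RNA and DNA, and libraries were sequenced with 150 bp reads. Per the submitters' processing notes, the authors used fastp, edgeR and limma with build hg38; the aligner, the barcode matching and the order of the steps are not stated. The 8 tables hold 4 columns of signal values, DNA and RNA replicates 1 and 2, whose unit and scaling the deposited headers do not name. Within each column, 100% of the signal values were whole multiples of 1 step (tolerance 0.02), as reads divided by 1 factor per column would be. The step was therefore taken as 1 read to obtain the depths and reads per element given with the results. The log2 fold changes of RNA over DNA and the mean log2 levels are from the authors' limma fit, per the file headers. The score columns, a moderated t and a log odds, are also from the authors' limma fit, and the log odds were not used here. Raw and adjusted p-values are from the authors' limma fit, per the file headers; the method of adjustment is not stated.

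Elements were grouped into classes by the leading letters of their names, and orientation and substitution were read from the names. The authors' log2 fold changes and calls at an adjusted p under 0.05 were used for counts, relations, classes and substitutions. For named elements, the log2 RNA/DNA ratio was computed for each replicate with 0.5 reads added, and is given as mean and SD over 2 replicates. This ratio differed from the authors' log2 fold change by at most 0.0704. Elements that the authors listed without a test, 3 to 11 per table, were left out; their values were all below 10.

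Pearson's r and Spearman's rho were tested by two-sided permutation with 100000 resamples (10000 for alternatives), and 95% intervals of r and slopes are from 2000 bootstrap draws of elements. Classes of at least 30 elements were compared with all other elements of the table by a two-sided permutation test of the difference of means. The same test of percentile ranks, promoter minus enhancer, was added after the data were seen. Overlap of calls was tested by Fisher's exact test, two-sided. A substituted element was compared with its wild type by a z test with standard errors from the authors' log2 fold change and t, and signs by an exact sign test. A z test of the promoter minus the enhancer change over the pairs measured in both read-outs was added after the data were seen. Benjamini-Hochberg adjustment was made within each family of relations, classes or pairs. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.

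Comparisons, tests, part of the alternatives and the rule for named elements were set before the data were examined. The rule takes, per table, the 10 highest and 5 lowest called elements, 1 per locus; per pair of read-outs, the 5 called elements most shifted in percentile rank either way; per pair of minimal promoters, the 3 elements with the largest standardised difference either way; and the 5 largest falls and rises among called substitutions. A part of these is named in the text. KSUAT0022, KUUAE0129_TG174GT.fwd and KUUAE0071_T12C.fwd where the rule does not name them were chosen after their values were seen. Alternatives were a stricter threshold, a minimum fold, other zero points, own limma fits on the log2 signals with and without a replicate block and with 1 library left out, other reads added, 1 element per locus, only active or precise elements, single replicates and medians. The setting of 1 element per locus also left out the substituted elements.

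The own limma fit was tested on simulated data with log2 changes of 0.5, 1 and 2 put into 67, 67 and 66 elements of each table. Far fewer elements were thus changed than were called in the real data, so the adjusted cut-off was stricter in the simulation. RNA values were drawn around the DNA means, with noise pooled over DNA and RNA replicates. Changes of 0.5 were recovered for 94.0% and 92.5% of the elements in the promoter and enhancer read-outs of set 1, 91.0% and 65.7% for pMYC in set 2, 95.5% and 85.1% for pGAPDH, and 97.0% and 52.2% for pAPOBEC3F. Changes of 1 were recovered for 97.0%, 98.5% and 83.6% of the elements in the enhancer read-outs of pMYC in set 2, pGAPDH and pAPOBEC3F and for 100.0% in the other tables. Changes of 2 were recovered for 98.5% in the pAPOBEC3F enhancer read-out and 100.0% elsewhere. False calls made up 1.00% to 5.50% of the calls of a table. On simulated data without a relation, the permutation tests of a correlation and of a class called 5.50% and 6.50%, and the z test without a change called 5.90%.

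Tests of promoter-proximal elements, sequence motifs, GC content and gene lists were not run, because the tables give no coordinates, sequences or gene names of the elements. The names mark no negative controls, so the planned centring used all elements, and centring on the elements named by a number alone was added. Groups of 2 libraries are too small for a test of other splits or of outlying libraries.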

Results

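QUASARR-seq is a massively parallel dual-reporter assay that reads the promoter and the enhancer activity of the same DNA element, here after electroporation of plasmid libraries into K-562 cells, an established human leukaemia line. Each plasmid carried an element and a pair of barcodes, named paBC and eaBC. RNA over DNA reads of the paBC were taken as the promoter read-out and those of the eaBC as the enhancer read-out. Set 1 placed its elements with the minimal promoter pMYC. Set 2 held elements with pGAPDH, pMYC and pAPOBEC3F in 1 plasmid pool. Each read-out of each set had 2 RNA and 2 DNA libraries, 16 libraries in all. A further 3 plasmid index libraries have no table of values and were not used here. The deposited tables number 8, 1 per minimal promoter, set and read-out, with 3422 different element names. The tables of the 3 minimal promoters of set 2 come from the same libraries. The labels do not say whether replicates 1 and 2 are biological or technical, so the p-values of limma and of the z tests measure only the spread between these libraries.

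Read totals differed strongly between read-outs and minimal promoters. In set 1 the promoter read-out held 6617407 to 6916053 RNA reads per library and 10701434 to 10880944 DNA reads. The set 1 enhancer read-out held 1260027 to 1475068 RNA reads and 3032786 to 3052549 DNA reads. For pGAPDH, the RNA libraries held 9080385 to 10167588 promoter reads and 2930240 to 3142007 enhancer reads. For pMYC in set 2 they held 2116336 to 2360455 promoter reads and 409486 to 434897 enhancer reads. The lowest depth was that of the pAPOBEC3F enhancer read-out, with 200722 to 217209 RNA reads per library and a median of 49 and 53 reads per element. The pAPOBEC3F promoter read-out had 1679872 to 1802390 RNA reads. The correlation of the log2 RNA/DNA ratio between replicates, across elements, was 0.993 and 0.978 for the promoter and enhancer read-outs of set 1. It was 0.982 and 0.856 for pMYC in set 2, 0.979 and 0.798 for pGAPDH, and 0.985 and 0.801 for pAPOBEC3F. The reads are PCR reads without molecular identifiers and are not independent molecules. Intervals of r and of slopes come from draws of elements and cover neither counting error nor the spread between libraries.

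Which elements raise RNA over DNA was asked in each read-out. The strongest promoters included KSSAT0004.rev, which was among the 10 highest elements of every promoter and enhancer table, and TRE5GCLR0189.rev, which was among the highest promoters under all 3 minimal promoters of set 2. The lowest elements mostly carried names that begin with KNG, TRE5NGCC, TRE5SPN or TRE6_200S. Under pMYC and pAPOBEC3F more elements were called higher than lower, and the pGAPDH promoter read-out had more lower than higher calls at the authors' zero point. In the authors' deposited table for the set 1 promoter read-out, 857 of 1528 elements were higher and 398 lower at an adjusted limma p under 0.05. The authors' deposited table for the set 1 enhancer read-out had 835 of 1528 higher and 181 lower. For pMYC in set 2, the authors' deposited table had 1339 of 2561 promoter values higher and 712 lower, and 1035 of 2561 enhancer values higher and 189 lower. For pGAPDH, the authors' deposited table had 1105 of 3044 promoter values higher and 1420 lower, and 677 of 3043 enhancer values higher and 564 lower. For pAPOBEC3F, the authors' deposited table had 1369 of 2699 promoter values higher and 825 lower, and 810 of 2695 enhancer values higher and 199 lower.

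The counts of lower elements depended on the zero point. They also differed in fits with 1 library left out, mostly by whether a DNA or an RNA library was dropped. Such a fit takes its residual spread only from the arm that keeps 2 libraries. Its counts thus do not show the weight of a single library. Negative controls are not marked in the names, so values were also centred on the median of all elements of a table and, in a choice made after the data were seen, on that of the elements named by a number alone. Centring on all elements puts equal numbers of values on either side by construction, so shares of calls near 50% follow from it and say nothing about a balance of activity. In the promoter read-out, higher elements then made up 50.6% of the calls of set 1 (715 higher, 697 lower) against 68.3% without centring, 51.3% for pMYC in set 2 (1105 and 1047) against 65.3%, and 51.6% for pAPOBEC3F (1230 and 1156) against 62.4%. In the enhancer read-out, the share was 53.7% in set 1 (684 and 590) against 82.2%, 59.2% for pMYC in set 2 (786 and 541) against 84.6%, and 68.3% for pAPOBEC3F (710 and 329) against 80.3%. Centring on the numbered elements, which fixes no share, gave 81.2% in the set 1 promoter read-out (1042 and 242) and 78.2% in the set 2 pMYC promoter read-out (1603 and 446). Under pGAPDH both ways of centring moved the share by fewer than 10 points. The pGAPDH promoter read-out had 1307 higher and 1259 lower calls when centred on the numbered elements, and 197 higher and 179 lower with an absolute log2 fold change of at least 1, so its excess of lower calls held at the authors' zero point without a minimum fold only. In limma fits with 1 library left out, the set 1 promoter read-out had 253 lower elements without DNA replicate 1 and 265 without DNA replicate 2. Lower enhancer elements of set 1 numbered 76 without DNA replicate 1, 66 without DNA replicate 2 and 309 without RNA replicate 1. For pMYC in set 2 the lower enhancer elements numbered 58 and 59 without DNA replicates 1 and 2, and 314 and 308 without RNA replicates 1 and 2. For pGAPDH the lower enhancer elements numbered 280 without RNA replicate 2. For pAPOBEC3F the lower enhancer elements numbered 47 and 35 without DNA replicates 1 and 2, and 495 and 480 without RNA replicates 1 and 2, and the higher ones 529 without DNA replicate 1.

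Among the named elements of set 1, the highest promoter value was that of CMV584_GG543TT.fwd, with a log2 RNA/DNA ratio of 7.05 ± 0.10 (SD, n = 2). KSSAT0004.rev followed at 5.66 ± 0.11, and KSSAT0010.rev, KSSAT0024.rev and KSUAT0092.fwd at 5.41 ± 0.12, 5.37 ± 0.09 and 5.32 ± 0.06 (SD, n = 2 each). The lowest promoter value of set 1 was that of KNGUT0012.rev, at -1.68 ± 0.10 (SD, n = 2). In the set 1 enhancer read-out, KSSAT0006.fwd stood at 5.23 ± 0.00 and CMV584_GG546TT.rev at 5.20 ± 0.17 (SD, n = 2 each). KSSAT0024.rev and KSSAT0004.rev reached 4.96 ± 0.11 and 4.90 ± 0.00 (SD, n = 2 each), and both were also among the highest promoters. The lowest enhancer value of set 1, -1.17 ± 0.23 (SD, n = 2), was that of an element named by a number alone.

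In set 2, the pMYC promoter read-out was led by TRE5GCLR0189.rev at 7.25 ± 0.17 and TRE6_020S0033.rev at 7.23 ± 0.02 (SD, n = 2 each). RSV.fwd reached 4.83 ± 0.01 in the pMYC promoter and 3.48 ± 0.00 in the pMYC enhancer read-out (SD, n = 2 each). The highest pMYC enhancer value was again that of KSSAT0006.fwd, at 4.78 ± 0.12 (SD, n = 2). Under pGAPDH, TRE5GCNC0054.rev had the highest promoter value, 6.42 ± 0.04, and TRE5GCCC0106.fwd the highest enhancer value, 2.18 ± 0.04 (SD, n = 2 each). The lowest pGAPDH promoter value was that of TRE5GCLR0149.fwd, at -2.26 ± 0.04 (SD, n = 2). Under pAPOBEC3F, TRE5GCLR0189.rev and TRE6_060S0005.rev led the promoter read-out at 7.11 ± 0.28 and 6.86 ± 0.20, and KSSAT0006.fwd the enhancer read-out at 5.19 ± 0.04 (SD, n = 2 each). TRE6_200S0061.rev was among the 5 lowest in 4 tables, with -1.98 ± 0.16 in the pGAPDH promoter read-out from 324 RNA reads and -2.80 ± 0.48 in the pAPOBEC3F promoter read-out from 7 RNA reads (SD, n = 2 each). The 5 lowest called elements of the pAPOBEC3F enhancer read-out had 1 to 3 RNA reads over both replicates, so their order was not detectable at this depth. KSSUT0008.rev, among the 10 highest of that table, rested on 4 RNA reads and 1 DNA read.

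Whether the same DNA acts as promoter and as enhancer was asked by setting the read-outs side by side. Promoter and enhancer values rose together across elements under every minimal promoter. Many elements called higher as promoters under pGAPDH and pAPOBEC3F were not called higher as enhancers, where weak changes were recovered less often. KSSAT0004.rev and KSSAT0024.rev were among the 10 highest in both read-outs of pMYC in both sets. The relation was tightest with pMYC and loosest with pGAPDH. By mean percentile rank, the classes KSSAT and KSUAT stood higher among promoters than among enhancers in all 4 pairs of tables. TRE5NGCC stood lower among promoters in all pairs of set 2. Across elements, which are not independent replicates, Pearson's r between the log2 fold changes was 0.854 in set 1 (rho 0.890, 1525 elements, 95% interval 0.834 to 0.874). It was 0.836 for pMYC in set 2 (rho 0.824, 2554 elements, 0.820 to 0.850), 0.765 for pAPOBEC3F (rho 0.772, 2691 elements, 0.745 to 0.783), and 0.616 for pGAPDH (rho 0.662, 3039 elements, 0.581 to 0.646). Each of the 4 relations, by r and by rho, had a two-sided permutation p of 1.0e-05, the smallest 100000 resamples can give, and an adjusted p of 1.0e-05. Within single classes of element names r ranged from 0.405 (KNGAE) to 0.882 (KSUAT) in set 1, from 0.371 (KNGAT) to 0.873 (TRE6_HRHP) for pMYC in set 2, from 0.337 (TRE5SPNN) to 0.744 (KUUAE) for pGAPDH and from 0.328 (KNGAT) to 0.802 (KUUAE) for pAPOBEC3F, so the values over all elements do not hold for every class. Divided by the root of both reliabilities, r over all elements was 0.860 in set 1, 0.869 for pMYC in set 2, 0.657 for pGAPDH and 0.807 for pAPOBEC3F. The mean rank difference of KSSAT minus that of all other elements was 7.22 percentile points in set 1, 5.20 for pMYC in set 2, 10.5 for pGAPDH and 5.88 for pAPOBEC3F, with adjusted permutation p-values of 3.7e-05, 0.0079, 2.2e-04 and 0.0031 over the classes of each pair. That of TRE5NGCC was -6.76, -5.12 and -8.72 points for pMYC in set 2, pGAPDH and pAPOBEC3F (adjusted permutation p 2.0e-04, 0.0038 and 5.0e-05). Other classes shifted too, TRE6_200S by -16.2 points for pGAPDH and TRE6_HPHP by 12.2 for pAPOBEC3F. KNGAE shifted by 6.87 points for pGAPDH and by -9.12 for pAPOBEC3F. In set 2 the enhancer read-out was less reliable (0.887 to 0.932, against 0.990 to 0.994), which pulls ranks of high and low classes to the middle. For pMYC in set 2, mean ranks were 88.7 and 83.8 for KSSAT and 24.8 and 31.0 for TRE5NGCC as promoters and enhancers. In set 2 a preference of these classes for a read-out was thus not told apart from noise. In set 1 the reliabilities were 0.997 for promoters and 0.990 for enhancers, which argues against replicate noise as the cause there. KSUAT shifted by 6.89 points in set 1, and the low classes KNGAE, KNGAT and KNGUT by -2.6, 0.60 and 0.62. The substituted elements shifted by -8.78 points in set 1, which displaces other ranks, so a preference of KSSAT and KSUAT stays open there. The tables were normalized separately, so a relation was tested and no difference in level.

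**Figure D1:**
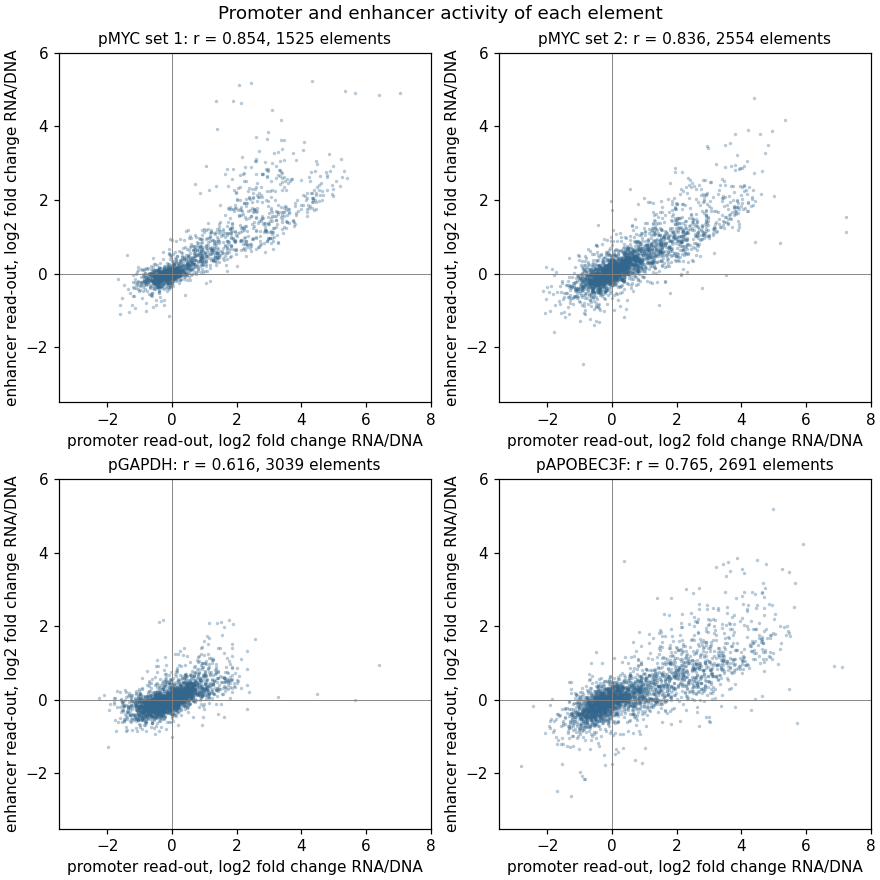
Log2 fold change of RNA over DNA in the promoter read-out (x axis) and the enhancer read-out (y axis) for each element, 1 panel per minimal promoter and set. Points run along a rising band in all 4 panels, with r from 0.616 under pGAPDH to 0.854 for pMYC in set 1.

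Calls overlapped in the same way. In set 1, 755 elements were called higher in both read-outs, 102 only in the promoter and 80 only in the enhancer read-out, with an odds ratio of 54.4 (Fisher's exact test, p 1.2e-215, adjusted 1.6e-215). For pMYC in set 2 the counts were 959, 379 and 76 (odds ratio 38.0, exact p 1.0e-280, adjusted 4.0e-280). For pGAPDH they were 560, 544 and 117 (odds ratio 15.996, exact p 6.6e-178, adjusted 6.6e-178), and for pAPOBEC3F 772, 592 and 38 (odds ratio 44.2, exact p 3.9e-236, adjusted 7.8e-236). Of the elements called higher in the enhancer read-out, 90.4%, 92.7%, 82.7% and 95.3% were also called higher in the promoter read-out of set 1, set 2 pMYC, pGAPDH and pAPOBEC3F. Of those called higher in the promoter read-out, 88.1%, 71.7%, 50.7% and 56.6% were also called higher in the enhancer read-out. Changes of 0.5 put into simulated data were recovered for 52.2% of the elements in the pAPOBEC3F enhancer and 97.0% in its promoter read-out, and for 85.1% and 95.5% under pGAPDH. The simulation changed far fewer elements than were called, so its cut-off was stricter and these shares are not those of the authors' calls. The higher pAPOBEC3F enhancer calls ranged from 529 to 1009 with 1 library left out. A missing enhancer call thus does not show missing enhancer activity. With a log2 fold change of at least 1 the odds ratios were 191, 98.1, 21.3 and 76.4, in the same order. Calls of opposite direction were few: 7 elements of set 1 were higher as promoter and lower as enhancer, and 19 were the reverse. For pGAPDH these counts were 36 and 60.

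Some elements stood apart. TRE5SPNN0002.rev had a promoter log2 RNA/DNA ratio of 2.79 ± 0.16 and an enhancer ratio of -0.39 ± 0.06 with pMYC in set 2, and 0.96 ± 0.09 and -0.47 ± 0.06 with pGAPDH (SD, n = 2 each). TRE5SPNR0019.rev had 1.60 ± 0.06 as promoter and -0.46 ± 0.24 as enhancer with pGAPDH, and 5.72 ± 0.02 and -0.61 ± 0.70 with pAPOBEC3F (SD, n = 2 each), the last value from 21 RNA reads. TRE5GCLR0030.fwd had 3.51 ± 0.02 as promoter and -0.04 ± 0.18 as enhancer with pMYC in set 2 (SD, n = 2 each). In set 1, KUUAE0051.rev had 1.06 ± 0.14 as promoter and -0.26 ± 0.00 as enhancer (SD, n = 2 each). On the enhancer side, KUUUT0102_G280A.rev of set 1 had -1.39 ± 0.10 as promoter and 0.50 ± 0.12 as enhancer, and TRE6_HRHR0059.fwd with pGAPDH had -0.77 ± 0.08 and 0.79 ± 0.01 (SD, n = 2 each). TRE6_HPHP0013.fwd with pGAPDH had -0.92 ± 0.00 as promoter and 0.59 ± 0.10 as enhancer (SD, n = 2 each). TRE5NGCC0139.rev, at the enhancer end with pMYC in set 2, rested on replicate 1: its enhancer ratio was 1.34 ± 2.24 (SD, n = 2) and turned to -0.24 without replicate 1.

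How far activity depends on the minimal promoter was asked with the elements of set 2 shared between tables. Element order was shared in both read-outs, most closely between pMYC and pAPOBEC3F. Values under pGAPDH spanned a narrower range: a KSSAT element such as KSSAT0004.rev reached 5.34 ± 0.02 as promoter under pMYC, 5.91 ± 0.03 under pAPOBEC3F and 2.57 ± 0.07 under pGAPDH (SD, n = 2 each). KSSAT0014.fwd was high as promoter under pMYC (4.44 ± 0.06) and pAPOBEC3F (4.90 ± 0.29) and not under pGAPDH (-0.16 ± 0.41; SD, n = 2 each). TRE5GCNC0053 lay above the zero point of pMYC and below that of pGAPDH in both orientations. Its promoter ratios were 1.48 ± 0.01 and -0.92 ± 0.07 for the fwd and 1.21 ± 0.06 and -1.01 ± 0.02 for the rev element (SD, n = 2 each). KNGAT0110.rev was relatively lower under pMYC, with -1.85 ± 0.02 against -0.09 ± 0.01 under pGAPDH (SD, n = 2 each). KNGAT0105.fwd had -0.84 ± 0.03 under pMYC and 1.82 ± 0.19 under pAPOBEC3F (SD, n = 2 each). In the enhancer read-out TRE6_HRHR0016.fwd reached 3.85 ± 0.25 under pAPOBEC3F, 2.40 ± 0.14 under pMYC and 0.51 ± 0.08 under pGAPDH (SD, n = 2 each). Values of each minimal promoter were normalized separately, so they rank elements within it and give no difference in level between minimal promoters. In promoter reads, KSSAT0004.rev had 4216 RNA and 384 DNA reads under pMYC and 33648 and 3499 under pGAPDH. TRE5GCNC0053.fwd had 233 and 309 under pMYC and 1704 and 1992 under pGAPDH. RNA per DNA read thus did not follow the gap in ratios.

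Across elements, which are not independent replicates, r between promoter values was 0.967 for pMYC and pAPOBEC3F (rho 0.944, 2279 elements), 0.837 for pMYC and pGAPDH (rho 0.787, 2469 elements) and 0.782 for pGAPDH and pAPOBEC3F (rho 0.711, 2599 elements). Between enhancer values r was 0.864 for pMYC and pAPOBEC3F (rho 0.782, 2279 elements), 0.771 for pMYC and pGAPDH (rho 0.692, 2468 elements) and 0.778 for pGAPDH and pAPOBEC3F (rho 0.692, 2595 elements). All 6 relations, by r and rho, had a two-sided permutation p of 1.0e-05, the smallest 100000 resamples can give, and an adjusted p of 1.0e-05. The slope of the orthogonal regression of pGAPDH on pMYC values was 0.455 (95% interval 0.438 to 0.473) in the promoter and 0.363 (0.344 to 0.383) in the enhancer read-out. The slope of pAPOBEC3F on pMYC values was 1.23 (1.21 to 1.24) in the promoter and 1.02 (0.994 to 1.05) in the enhancer read-out. The slope of pAPOBEC3F on pGAPDH values was 2.91 (2.81 to 3.02) and 2.77 (2.63 to 2.93).

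**Figure D2:**
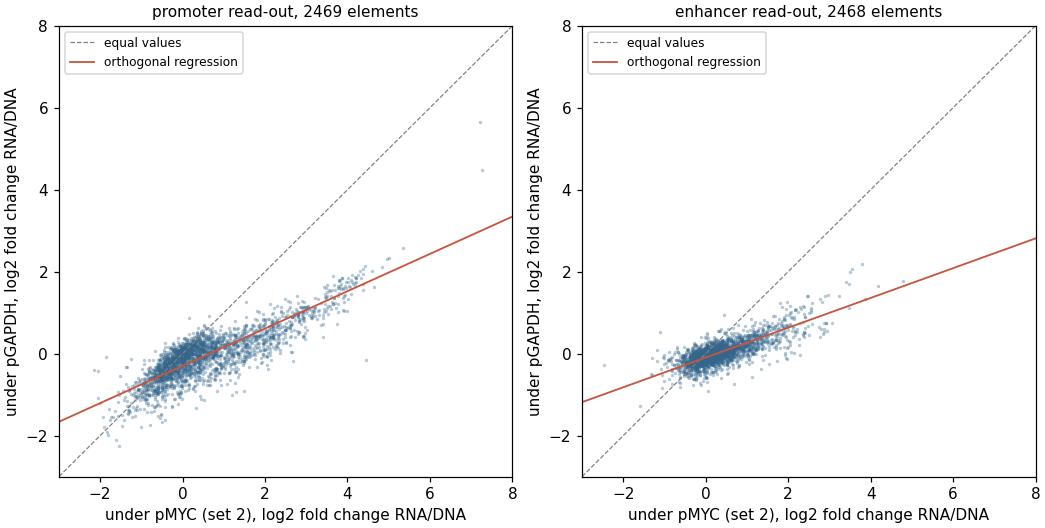
Log2 fold change of RNA over DNA under pMYC in set 2 (x axis) and under pGAPDH (y axis) for each shared element, with the orthogonal regression and the line of equal values. The regression is flatter than the line of equal values in the promoter (slope 0.455) and the enhancer read-out (slope 0.363).

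The elements shared by set 1 and set 2 under pMYC gave a repeat with another plasmid pool. KSSAT0004.rev and KSSAT0024.rev were among the 10 highest promoters of both sets, at 5.66 ± 0.11 and 5.37 ± 0.09 in set 1 and 5.34 ± 0.02 and 4.96 ± 0.10 in set 2 (SD, n = 2 each). KSSAT0006.fwd was the highest enhancer in both sets. Across 1137 shared elements, which are not independent replicates, r between promoter values was 0.969 (rho 0.942, 95% interval 0.963 to 0.974), and across 1139 elements r between enhancer values was 0.901 (rho 0.824, 0.882 to 0.917). Both relations, by r and rho, had a two-sided permutation p of 1.0e-05, the smallest 100000 resamples can give, and an adjusted p of 1.0e-05. Slopes of set 2 on set 1 values were 0.862 (0.848 to 0.876) and 0.865 (0.837 to 0.894).

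Whether activity depends on the orientation of the element was asked with elements present as fwd and rev. Values of the orientations rose together in all 8 tables. KSUAT0022, for example, had a promoter ratio of 3.62 ± 0.08 as fwd and 2.83 ± 0.16 as rev in set 1, and an enhancer ratio of 1.65 ± 0.00 and 1.52 ± 0.00 (SD, n = 2 each). TRE5GCNC0053 lay below the zero point of the pGAPDH promoter read-out in both orientations. Across elements, which are not independent replicates, r between orientations was 0.907 (rho 0.897, 711 elements) in the promoter and 0.891 (rho 0.876, 711 elements) in the enhancer read-out of set 1. It was 0.822 (rho 0.791, 1086 elements) and 0.700 (rho 0.671, 1086 elements) for pMYC in set 2, 0.619 (rho 0.586, 1429 elements) and 0.691 (rho 0.594, 1430 elements) for pGAPDH, and 0.862 (rho 0.856, 1192 elements) and 0.674 (rho 0.639, 1188 elements) for pAPOBEC3F. All 8 relations, by r and rho, had a two-sided permutation p of 1.0e-05, the smallest 100000 resamples can give, and an adjusted p of 1.0e-05. Among elements called higher in at least 1 orientation, r was lower, with 0.851 and 0.836 in the promoter and enhancer read-outs of set 1, 0.751 and 0.573 for pMYC in set 2, 0.398 and 0.605 for pGAPDH, and 0.754 and 0.478 for pAPOBEC3F. This choice rests on the values correlated and drops pairs low in both orientations, which lowers r by itself. It does not show that active elements depend more on orientation. Over all elements, the promoter r minus the enhancer r was 0.0156 (95% interval -0.0163 to 0.0513) in set 1, 0.124 (0.0723 to 0.174) for pMYC in set 2, 0.187 (0.133 to 0.248) for pAPOBEC3F and -0.0718 (-0.133 to -0.0101) for pGAPDH. The pGAPDH difference was -0.0149 without replicate 1 and -0.0070 without replicate 2, and in rho it was -0.0066 (-0.0509 to 0.0360).

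Element names fall into classes by their leading letters, whose meaning is not given in the sources used here. By their medians, KSSAT and KSUAT were the most active promoter classes of set 1, and in its enhancer read-out the elements with a substitution in their name came before both. In set 2 the classes TRE6_HRHP, TRE6_HPHP and TRE6_HRHR stood beside KSSAT and KSUAT. Classes KNGAE, KNGAT, KNGUT and TRE5NGCC were the least active in both read-outs under pMYC. All 128 KSSAT elements of set 1 were called higher as promoters, with a median log2 fold change of 3.18, and 125 of 128 as enhancers, with a median of 1.47. The KSUAT elements of set 1 had medians of 2.67 and 1.12. The KNGAE, KNGAT and KNGUT promoter medians of set 1 were -0.39, -0.37 and -0.29, and 67.5%, 67.6% and 61.5% of their elements were called lower. Elements with a substitution in their name had medians of 1.99 as promoters and 1.80 as enhancers. For pMYC in set 2 the promoter medians were 2.58 for KSSAT, 2.14 for TRE6_HRHP, 2.05 for KSUAT, 1.94 for TRE6_HPHP, 1.36 for TRE6_HRHR and -0.38 for TRE5NGCC. Under pAPOBEC3F they were 3.32 for KSSAT, 2.76 for TRE6_HRHP, 2.74 for TRE6_HPHP, 2.68 for KSUAT and 2.15 for TRE6_HRHR, and under pGAPDH 0.72, 0.45, 0.31, 0.44 and 0.12. Under pGAPDH the classes TRE5SPNN, TRE5SPON and TRE6_200S had the lowest promoter medians, -0.61, -0.64 and -0.59, from 58, 37 and 38 elements.

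**Figure D3:**
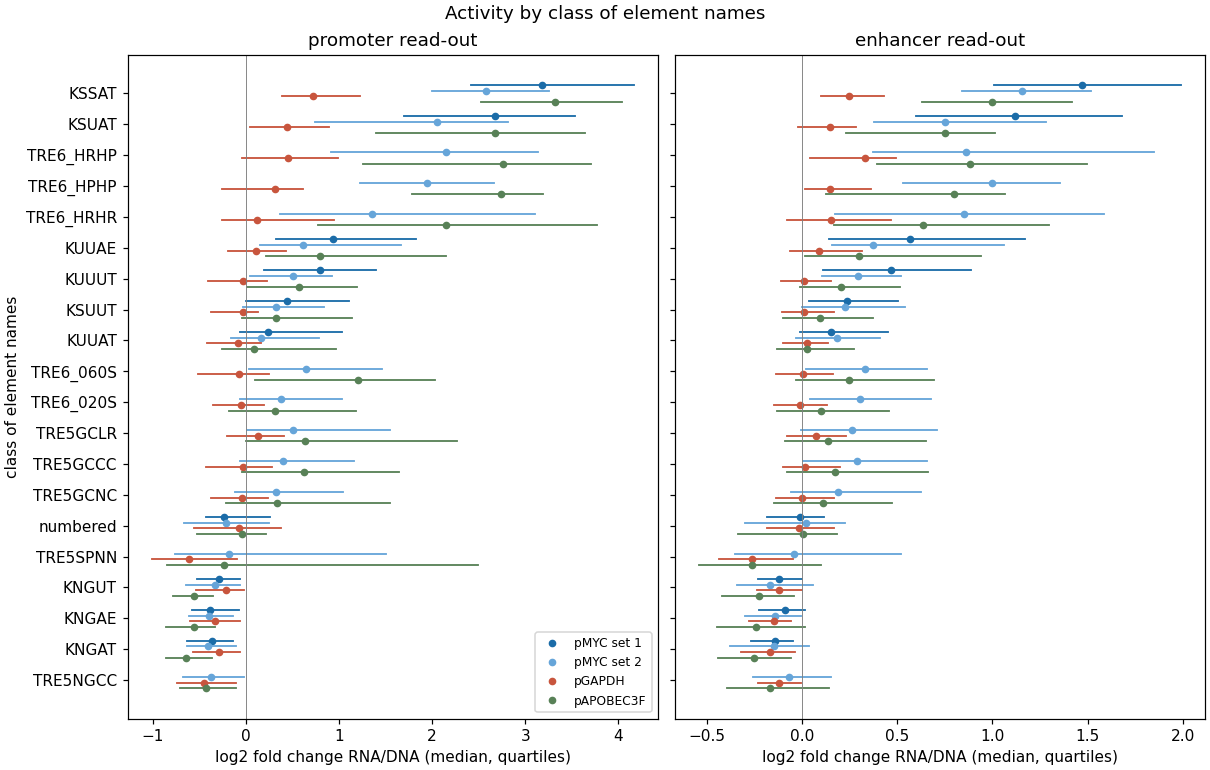
Median (point) and quartiles (line) of the log2 fold change of RNA over DNA for 20 classes of element names, in the promoter (left) and enhancer (right) read-out, coloured by minimal promoter and set. KSSAT medians lie between 0.72 and 3.32 in the promoter read-out, and KNGAE, KNGAT, KNGUT and TRE5NGCC medians lie below 0 in each table that holds them.

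Each class of at least 30 elements was set against all other elements of its table by a two-sided permutation test of the difference of means, adjusted over the classes of the table. KSSAT, KSUAT, KNGAE, KNGAT and KNGUT passed in all 8 tables, and TRE5NGCC, TRE6_HPHP, TRE6_HRHP and TRE6_HRHR in all 6 tables of set 2. The KSSAT mean lay above that of the others by 2.47 and 1.05 in the promoter and enhancer read-outs of set 1, by 2.12 and 0.93 for pMYC in set 2, by 0.88 and 0.25 for pGAPDH, and by 2.62 and 0.91 for pAPOBEC3F. The permutation p of each of these was 1.0e-05, the smallest 100000 resamples can give, with adjusted values from 1.6e-05 to 2.5e-05. Higher and lower classes numbered 4 and 6 of 11 in the promoter read-out of set 1, 8 and 6 of 20 for pMYC in set 2, 7 and 7 of 22 for pGAPDH, and 8 and 6 of 20 for pAPOBEC3F. In the enhancer read-out they numbered 3 and 6 of 11, 7 and 5 of 20, 8 and 6 of 22, and 7 and 7 of 20. KSUUT passed as lower in both read-outs of set 1 by the mean (-0.35 and -0.26), while its median lay above that of the others by 0.06 and 0.01. The setting of 1 element per locus also dropped the substituted elements, with set 1 means of 1.95 as promoters and 1.78 as enhancers. Changes under it in set 1 were thus not told apart from a changed comparison group. With 1 element per locus the KSUUT call was lost in both read-outs of set 1, the TRE5GCCC call in the pMYC enhancer read-out of set 2 and the KSUAT call in the pGAPDH enhancer read-out. So was the KUUAT call in both read-outs of set 1, in the pMYC promoter read-out of set 2 and in the pAPOBEC3F enhancer read-out, and the KUUAE call in the pMYC and pAPOBEC3F promoter read-outs of set 2. Without replicate 1, calls were lost for KUUAE in the set 1 promoter read-out (difference 0.24, adjusted permutation p 0.0638), for TRE6_060S in the pMYC promoter (0.26, 0.0557) and TRE5GCCC in the pMYC enhancer read-out of set 2 (0.10, 0.0817), and for KUUAT in the pAPOBEC3F enhancer read-out (-0.13, 0.0691). Calls were gained for KUUAE in the set 1 enhancer read-out with 1 element per locus (0.42, adjusted permutation p 1.7e-04, against 0.16 and 0.0731), for TRE6_200S in the pGAPDH enhancer read-out without replicate 1 (-0.12, 0.0465, against -0.09 and 0.1525) and for TRE6_060S in the pAPOBEC3F enhancer read-out without replicate 2 (0.17, 0.0412, against 0.15 and 0.0652).

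Set 1 also held 209 elements with a named substitution in each read-out. Of these, 25 could be set against their wild type in the promoter read-out and 24 in the enhancer read-out. The pairs come from 8 and 7 elements, counted without orientation, so the results cover only a small part of the substituted elements. The substituted elements of KSUAT0022 lay below their wild type in both read-outs, and so did KUUAE0129_A73G.fwd, which had the largest fall in the enhancer read-out. The changes of KSUAT0022 share the same wild-type value in each orientation, and their z tests hold only the spread between replicates, not error of a construct or pool. Its rev wild type had a promoter ratio of 2.83 ± 0.16 in set 1 and 2.26 ± 0.03 in the separately normalized set 2 (SD, n = 2 each). That gap is about as large as the promoter fall of KSUAT0022_A212G.rev. Set 2 values were lower among high elements generally. The slope of set 2 on set 1 promoter values was 0.862, and the KSUAT promoter median was 2.67 in set 1 and 2.05 in set 2. The gap is thus not told apart from a difference in scale between the tables and does not measure error of the wild type. Positions are numbered as in the element names, and the origin of the count is not given in the sources used here. KSUAT0022 fell with A209C, A212G, T213C and G214A, in each orientation in which the substituted element was measured. Promoter activity fell by 1.68 on the log2 scale for KSUAT0022_A212G.fwd, by 1.41 for KSUAT0022_A209C.fwd, by 1.39 for KSUAT0022_T213C.fwd and by 1.22 for KSUAT0022_G214A.fwd. Enhancer activity of the same elements fell by 0.77, 0.85, 0.76 and 0.86. The rev elements of A209C, A212G and T213C fell by 0.85, 0.54 and 0.84 as promoters and by 0.88, 0.63 and 0.86 as enhancers. KUUAE0129_A73G.fwd fell by 1.67 as promoter (SE 0.129) and by 2.08 as enhancer (SE 0.1798), while KUUAE0129_TG174GT.fwd fell by 0.22 as enhancer and its promoter change, -0.07, was not called. KUUAE0071_T12C.fwd fell by 0.81 as promoter and rose by 0.37 as enhancer. Its wild type had a promoter ratio of 1.87 ± 0.15 in set 1 and 1.17 ± 0.04 in set 2 (SD, n = 2 each). KUUAE0051_T223A.rev, whose wild type had an enhancer ratio of -0.26 ± 0.00 (SD, n = 2), rose by 0.67 as enhancer, and its promoter change, 0.04, was not called. In the promoter read-out KNGUT0054_C152T.fwd rose by 0.51, by 0.10 without replicate 2 and by 0.88 without replicate 1, and KUUAE0071_T7A.fwd rose by 0.22.

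**Figure D4:**
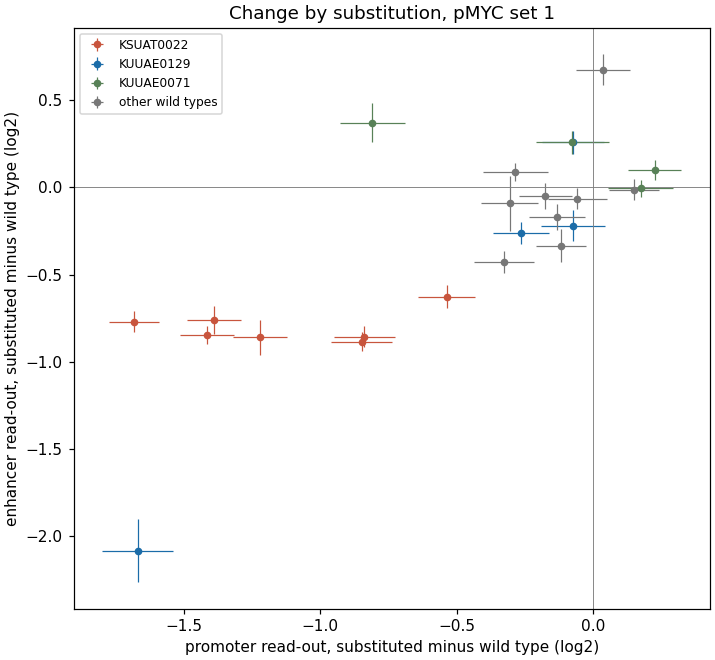
Change of the log2 fold change from the wild type to the substituted element in the promoter (x axis) and enhancer (y axis) read-out of set 1, with standard errors as bars, coloured by wild type. The KSUAT0022 substitutions lie in the lower left, between -1.68 and -0.54 as promoters, and KUUAE0071_T12C.fwd lies at -0.81 and 0.37.

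By a z test on the standard errors of the authors' limma fit, 13 of 25 promoter changes were lower and 2 higher at an adjusted p under 0.05, and 13 of 24 enhancer changes were lower and 4 higher. Changes were negative for 20 of 25 pairs in the promoter read-out (80.0%, exact sign test, two-sided p 0.0041) and for 18 of 24 in the enhancer read-out (exact p 0.0227). Without replicate 2 the enhancer share was 70.8% (exact p 0.0639). The pairs share wild types and are not independent: with 1 value per wild type, 9 of 13 promoter medians (exact p 0.2668) and 9 of 12 enhancer medians (exact p 0.1460) were negative. These wild types count both orientations of an element apart and come from 8 and 7 elements, so they are not independent either. Across the 24 pairs measured in both read-outs, r between the promoter and the enhancer change was 0.779 (two-sided permutation p 2.0e-05) and rho 0.747 (p 1.1e-04). This family held 1 relation, so the adjusted values equal the raw ones. Without KSUAT0022, r was 0.747 over 17 pairs, and over 12 wild types, which include both orientations of KSUAT0022, it was 0.769. The 17 pairs include KUUAE0129_A73G.fwd, at -1.67 as promoter and -2.08 as enhancer, far from the others. No r was computed without both KSUAT0022 and this pair, so a relation among the remaining substitutions is not shown. Both changes were called in the same direction for 10 pairs and in opposite directions for 1 pair, KUUAE0071_T12C.fwd.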

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

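The noise tests and the rho differences of the orientation pattern and the test of the difference between read-outs for the substitutions were chosen only after the result was seen. The correlation between orientations differed between read-outs: promoter minus enhancer r was 0.124 for pMYC in set 2 and 0.187 for pAPOBEC3F (rho differences 0.122 and 0.214), and -0.0718 for pGAPDH, where the difference in rho was -0.0066 (95% interval -0.0509 to 0.0360) and that in r -0.0149 without replicate 1 and -0.0070 without replicate 2, so a difference for pGAPDH depends on the measure. Larger noise between replicates is the technical explanation weighed for the lower enhancer r. For pAPOBEC3F the tables argue against it as the whole cause, since the difference was 0.123 (95% interval 0.0614 to 0.188) after correction for noise and 0.128 (0.0435 to 0.237) among the 371 elements with a standard error below the median in all 4 values. For pMYC in set 2 the corrected difference was 0.0793 (0.0297 to 0.131) but 0.0274 (-0.0209 to 0.0840) among 334 such elements, so noise and a difference between read-outs cannot be told apart there, because the estimate fell among these elements and its interval includes 0. Error from barcode sets or the plasmid pool, shared by both replicates, stays open, and no biological explanation was tested.

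KUUAE0071_T12C.fwd moved in opposite directions against its wild type. Its promoter value changed by -0.81 and its enhancer value by 0.37, each with the same sign in both replicates. Each change lies within a table, so a constant factor on the signals of a table cancels, and the difference of the changes was -1.18 (SE 0.162), past the threshold in a z test adjusted over 24 pairs (adjusted p 3.9e-12). Of the other pairs 7 differed too: KSUAT0022_A212G.fwd by -0.91, KSUAT0022_T213C.fwd by -0.63, KSUAT0022_A209C.fwd by -0.57, KSUAT0022_G214A.fwd by -0.36, KUUAE0051_T223A.rev by -0.64, KUUAE0118_G60C.rev by -0.37 and KUUAE0129_T213C.fwd by -0.33. A difference in scale between read-outs does not cancel: across elements of set 1 the SD was 1.49 in the promoter and 0.968 in the enhancer read-out. KSUAT0022.fwd itself stood at 3.62 as promoter and 1.65 as enhancer. The larger promoter falls of its substituted elements are thus not told apart from the wider range of that read-out. The rev elements of KSUAT0022 fell by similar amounts in both read-outs, with differences of 0.04 for A209C (SE 0.1247), 0.09 for A212G (SE 0.124) and 0.02 for T213C (SE 0.1265). The promoter value of the KUUAE0071_T12C.fwd wild type differed between sets, with 1.87 ± 0.15 in set 1 and 1.17 ± 0.04 in set 2 (SD, n = 2 each), a gap about as large as the fall, and the substituted element was measured in set 1 only, at 1.06 ± 0.00 (SD, n = 2). The slope of set 2 on set 1 promoter values was 0.862. Part of that gap between sets can thus come from the scale of the separately normalized tables. The cause was not tested, and no biological explanation was tested.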

How the results depend on the processing

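Alternatives with single replicates, own replicate means, 2 reads added, the authors' log2 fold change for named elements, numbered elements, a z test without centring, the own limma fit without a block (for the overlap also with one), differences in rho and 1 value per wild type were chosen only after the data were seen. Of the results that answer a comparison, 234 tested values under alternatives kept direction and side of the threshold and 3 were no longer past it, 222 counts stayed within 1.5 times and 42 did not, and 50 slopes or differences of r stayed in the 95% interval and 18 did not. A count within 1.5 times can hide a change of side: pGAPDH promoter calls, 1105 higher and 1420 lower, were 1291 and 1278 when centred on all elements. Of class differences 697 kept direction and side, 14 reversed, 14 were no longer past the threshold and 3 newly were, and 2 called ones reversed by the median. Of substitution changes 130 stayed within 1 SE and 17 did not, and of named elements 970 values stayed within 1 SD, 17 moved and 1 reversed. With an absolute log2 fold change of at least 1, fewer elements pass by construction: higher and lower promoter calls were 571 and 31 in set 1, 721 and 95 for pMYC in set 2 and 197 and 179 for pGAPDH, with 139 lower for pAPOBEC3F, and enhancer calls 392 and 4, 404 and 13, 52 and 2, and 360 and 30. At an adjusted p under 0.01, lower enhancer calls were 110, 90, 360 and 95, and higher promoter substitutions 0. Centred on all elements, which evens the sides by construction, lower calls were 697 and 590 in set 1, 541 in the set 2 pMYC enhancer and 329 in the pAPOBEC3F enhancer read-out; centred on numbered elements, 242 and 446 in the promoter read-outs of set 1 and set 2 pMYC. In own limma fits with 1 library left out, the lone library of an arm was assumed to vary like the others, and lower calls ranged from 253 to 507 in the promoter and 66 to 309 in the enhancer read-out of set 1. Lower enhancer calls ranged from 58 to 314 for pMYC in set 2, 280 to 572 for pGAPDH and 35 to 495 for pAPOBEC3F, with 529 to 1009 higher. Labels do not say what a replicate number marks, though each harvested pool was split into RNA and DNA; deviations of DNA and RNA correlated at -0.0743 to 0.408, and with a replicate block higher and lower calls were 842 and 387 in the set 1 promoter read-out and 734 and 603 in the pGAPDH enhancer read-out, with no count of any table moved by over 1.5 times. Slopes among active elements were 0.415 (pGAPDH on pMYC) and 3.17 (pAPOBEC3F on pGAPDH) in the promoter and 1.10 (pAPOBEC3F on pMYC) in the enhancer read-out; among low-error elements 0.419, 3.20 and, for pAPOBEC3F on pMYC, 1.24 in the promoter and 2.62 (2.6164, pAPOBEC3F on pGAPDH) in the enhancer read-out, and 0.834 and 0.8335 between sets. With 2 reads added the last enhancer slope between minimal promoters was 2.6209. With 1 replicate, enhancer slopes were 0.340 to 0.345, 1.03 to 1.05 and 2.97 to 3.07, and orientation differences of r 0.156 to 0.177 (pMYC set 2), -0.0149 to -0.0070 (pGAPDH, and -0.0066 in rho) and 0.243 to 0.255 (pAPOBEC3F). Among active wild types 1 promoter substitution was higher. With 1 value per wild type 69.2% and 75% of the changes were negative, and without replicate 1 or 2 70.8% to 75% in the enhancer read-out. With 1 element per locus, uncalled class differences reversed: KUUUT to 0.199 and 0.178 in set 1 and 0.0025 in the pGAPDH promoter, TRE5GCNC to 0.014 and 0.0076 and TRE6_020S to -0.0528 for pMYC in set 2, and numbered elements to 0.053 and 0.0138 for pGAPDH. In set 1 this setting also dropped the substituted elements, which changes the comparison group. By the median, KSUUT of set 1 turned to 0.0611 and 0.0102. TRE5GCNC turned to -0.0172 in the pAPOBEC3F enhancer read-out with 2 reads added. With 1 replicate, KUUUT ranged from -0.0265 to 0.0043 (set 1 promoter) and -0.0040 to 0.0486 (set 2 pMYC enhancer), TRE5GCNC from -0.0056 to 0.0047 (set 2 pMYC enhancer), -0.0075 to 0.0358 (pAPOBEC3F promoter) and -0.0005 to 0.0093 (pAPOBEC3F enhancer), and TRE5NGCC0139.rev from -0.24 to 2.92. Except where construction is named, the cause was not tested. Depth limits the pAPOBEC3F enhancer read-out most, where 268 and 246 elements had under 10 RNA reads.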

Other observations

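The read-through test, the noise test of the pGAPDH range, its tests with the middle group of elements and the TRE6 test were chosen only after the result was seen. Promoter and enhancer values were correlated across elements. An error shared by both barcodes of a plasmid pool is argued against as the whole cause, since promoter values of set 2 and enhancer values of set 1, from different pools, had r 0.887 (95% interval 0.872 to 0.901, 1133 elements). Transcripts that start in the element and run into the eaBC were also considered. The eaBC was taken to lie on the other side of the element from the paBC, as the names of the plasmid index libraries order them. The enhancer value correlated more with the promoter value of the same than of the opposite orientation, by 0.0441, 0.121, 0.108 and 0.0773 for set 1, set 2 pMYC, pGAPDH and pAPOBEC3F. Values of the same orientation come from the same plasmids and barcode pairs, so an error of a construct would give this too. The test thus cannot decide on such transcripts, and they stay open. A property of the sequence shared by both activities stays open, and no biological explanation was tested.

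Values under pGAPDH spanned a narrower range than under pMYC. Measurement noise is argued against, since the SD ratio after correction for noise was 0.502 (95% interval 0.490 to 0.515) in the promoter and 0.427 (0.408 to 0.443) in the enhancer read-out. By covariance with pAPOBEC3F values, the promoter slope of pGAPDH on pMYC values was 0.874, 0.112 and 0.518 in the lowest, middle and highest of 3 equal groups of elements by pAPOBEC3F value, with 0.4015 over all elements. A constant background under pGAPDH alone needs a slope that rises over these groups and a ceiling one that falls. The comparison set beforehand, highest minus lowest, was -0.356 (-0.435 to -0.272), as predicted for a ceiling and against a background as the whole cause. Of the comparisons added afterwards, middle minus lowest was -0.762 (-0.923 to -0.650). Highest minus middle was 0.406 (0.319 to 0.557), which a ceiling alone does not give. The comparisons for a ceiling thus point both ways and it stays open, as does a background as part of the cause. In the enhancer read-out highest minus lowest was -0.213 (-0.624 to 0.0101), so the comparison set beforehand did not decide there. Middle minus lowest was -0.4455 (-0.886 to -0.161) and highest minus middle 0.233 (0.0647 to 0.354). A background under pMYC and pAPOBEC3F stays open. A response that differs between minimal promoters, which the design names, stays open as untested.

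RNA reads per DNA read, summed over shared elements, differed between minimal promoters in the same libraries. In the promoter read-out they were 1.73 ± 0.114 under pGAPDH, 0.570 ± 0.0353 under pMYC and 0.476 ± 0.0133 under pAPOBEC3F (SD, n = 2 each). In the enhancer read-out they were 2.49 ± 0.155, 0.501 ± 0.0280 and 0.268 ± 0.0187 (SD, n = 2 each).

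TRE6_020S and TRE6_060S elements that share a number and orientation may be the same stretch of DNA in different lengths. Their values correlated across numbers, with r 0.830 and 0.641 in the promoter and enhancer read-outs of pMYC in set 2, 0.772 and 0.621 for pGAPDH, and 0.846 and 0.758 for pAPOBEC3F. The permutation p of each of the 6 relations was 1.0e-05, the smallest 100000 resamples can give, and so was the adjusted p. TRE6_060S minus TRE6_020S promoter values averaged 0.33 for pMYC, 0.55 for pAPOBEC3F and -0.02 for pGAPDH, with adjusted sign-flip permutation p-values of 3.0e-05, 3.0e-05 and 0.6524. Enhancer values differed by 0.05, 0.17 and 0.01 in the same order, with adjusted sign-flip permutation p-values of 0.6504, 0.0017 and 0.6504. The units were pairs of the same number and orientation, 87 to 104 per read-out and minimal promoter. Both orientations of a number thus entered as separate values although they are not independent, so these p-values can be too small.

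The wild types of the substitutions, except KUUAE0129.fwd, were also measured under pMYC in set 2, from another plasmid pool and in a table normalized separately. For KUUAE0129_A73G.fwd there is thus no such value of the wild type. KSUAT0022.fwd had a promoter log2 RNA/DNA ratio of 3.62 ± 0.08 in set 1 and 3.16 ± 0.01 in set 2, and an enhancer ratio of 1.65 ± 0.00 and 1.27 ± 0.11 (SD, n = 2 each). KSUAT0022.rev had promoter ratios of 2.83 ± 0.16 and 2.26 ± 0.03 and enhancer ratios of 1.52 ± 0.00 and 1.08 ± 0.18 (SD, n = 2 each). The largest gaps were those of KUUAE0071.rev, with promoter ratios of 2.25 ± 0.18 and 1.00 ± 0.14 and enhancer ratios of 2.91 ± 0.04 and 2.06 ± 0.03 (SD, n = 2 each). KUUAE0071.fwd had promoter ratios of 1.87 ± 0.15 and 1.17 ± 0.04 and enhancer ratios of 2.57 ± 0.08 and 1.96 ± 0.07, and KUUAE0051.fwd had enhancer ratios of 0.95 ± 0.01 and 0.31 ± 0.15 (SD, n = 2 each). KUUAE0051.rev had an enhancer ratio of -0.26 ± 0.00 in set 1 and -0.16 ± 0.26 in set 2 (SD, n = 2 each).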
